A study of Mus musculus with 8 samples.

How the data were processed

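RNA sequencing was performed on CD4+ T cells sorted from peritoneal washes of female mice that had carried ID8-Defb29/Vegf-A ovarian tumours, an aggressive mouse ovarian cancer model, for 20 days. The cells were gated on CD45, CD3 and CD4, per the labels' protocols. There were 8 libraries: 4 from mice with loxP-flanked Xbp1 and no Cre (WT) and 4 from mice that also carried Cd4-Cre, which deletes the flanked sequence in T cells (KO). Groups and replicate numbers were taken from the sample titles. The labels do not say whether each library came from a separate mouse, so p-values measure the spread between these libraries, part of which may be technical. Libraries were made with an ultra-low-input kit, per the labels' protocols.

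The authors deposited 1 table of estimated counts, whole numbers per gene and library, not normalized: the column totals differ, as do the upper quartiles. Bowtie 0.12.8, RSEM, edgeR and the build mm9 are named in the submitters' processing notes, with no role or order. RSEM estimates need not be whole, so the deposited expected counts had already been rounded if RSEM made them, and no further rounding changed them here. How reads that match several genes were shared, whether strand was used and how the 20909 rows were chosen is not given in the sources used here. Genes with near-identical copies and overlapping genes are therefore uncertain.

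Each row is a cluster of UCSC transcript identifiers, per the file headers. None of the 46809 identifiers matched the gene name tables at hand (0 matched), and the file does not pair them with gene names or coordinates. Rows are therefore reported by identifier, with at most 2 for each direction, and no gene name or position is given. Xbp1 was not located, so the deletion was not checked in the counts. The 39 gene lists that had been fixed for pathways, T cell states and other cell types were not tested (0 tested), including the lists for XBP1 targets, oxidative phosphorylation and glutamine use.

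The comparison of KO with WT used edgeR 4.0.16 in R 4.3.3: filterByExpr, TMM scaling, estimateDisp and a robust quasi-likelihood fit with group as the only term, over all 8 libraries. Tests were two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The standard error of a log2 fold change was the fold change divided by the square root of its F statistic. CPM values are scaled by the TMM factors. Principal components and correlations used log2 CPM with a prior count of 2. For genes detected at equal depth, each library was thinned at random to 23912043 reads, the smallest total. Single values per library were compared by exact permutation over all 70 arrangements of the 8 libraries, for which the smallest two-sided p is 0.0286. The position of KO replicate 1 on a gene was its distance from the WT mean as a share of the distance between the means of WT and of KO replicates 2 to 4, on log2(CPM + 0.5).

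The rule for single genes was the 10 largest changes in each direction among those past the threshold, or, where fewer than 5 qualified, the 10 with the smallest p. The second case applied. With no gene names, the 2 with the smallest p in each direction are given.

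Total counts ranged from 23912043 to 28643310 per library. A count of 0 allows up to 3 counts, which is 0.105 to 0.125 CPM, and such limits cover counting error only. The test was checked on simulated data with the means, library sizes and dispersions of the real libraries and known changes in a seeded set of genes. Genes were simulated as independent, each with 1 dispersion for both groups. With all 8 libraries, the quasi-likelihood test called 27 of 100 genes changed 2-fold and 68 of 100 changed 4-fold, and 1 of 15316 unchanged genes.

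The alternatives fixed before the data were examined were RLE factors or library size alone in place of TMM, no filter or a filter of at least 5 CPM in at least 4 libraries, DESeq2 1.42.0, limma 3.58.1 voom with sample quality weights, a fit without robust estimation, a block for the replicate number, and leaving out each library in turn. An edgeR exact test, the comparisons of detected gene clusters and of within-group correlation, and the other tools, scalings and omitted WT libraries run with KO replicate 1 left out were chosen after seeing the data. The replicate numbers were not taken to pair WT with KO libraries. The chi-square per gene between libraries of 1 group was at least 4.66, so no 2 of them differed by sampling noise alone. Whether 2 libraries came from 1 mouse is not given. All 8 were counted separately, as the labels list them, and a fit with WT replicates 3 and 4 summed into 1 library was added after seeing the data.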

Results

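The series measured gene expression in CD4+ T cells sorted from the peritoneal cavity of mice with ovarian tumours, and asked what changes when T cells lack XBP1, the transcription factor activated by the endoplasmic reticulum stress sensor IRE1α. Each group had 4 libraries. WT libraries held 27031960, 24455915, 25293603 and 28259927 estimated counts for replicates 1 to 4. KO libraries held 23912043, 28643310, 27874548 and 28107736. Of 20909 gene clusters, 28 had no count in any library and 16171 passed the low-count filter.

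In the comparison of all 4 KO with all 4 WT libraries, 1 gene cluster, uc007lys.1, rose in KO cells. It was close to absent from WT cells, at 0.122 CPM ± 0.172 (SD, n = 4), and reached 25.5 CPM ± 4.93 (SD, n = 4) in KO cells. The WT libraries held 1, 2, 0 and 11 counts of it, and the KO libraries 462, 741, 678 and 753. The log2 fold change was 7.62 with a standard error of 0.63 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.00221). It was 9.26 without WT replicate 4, which held most of the WT counts. In WT replicate 3, where the count was 0, the depth allows a level of up to 0.119 CPM. In the planned quasi-likelihood fit with a block for the replicate number, the cluster missed the threshold (adjusted p = 0.0672). All KO mice carried Cd4-Cre and no WT mouse did, so an effect of Cre cannot be told apart from loss of XBP1.

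No gene cluster fell past the threshold in this comparison (0 by the quasi-likelihood test). At an unadjusted p under 0.05, 875 were lower and 1108 higher in KO, a total of 1983 where chance alone would give 809. DESeq2 called 260 lower and 114 higher, and limma-voom with sample quality weights 282 lower and 158 higher. The edgeR exact test called 150 lower and 37 higher. For limma-voom chance cannot be excluded, since 8 of 35 splits of the 8 libraries, the real one included, gave as many calls. In the simulated data, DESeq2 called 27 of 15971 unchanged genes and the exact test 21 of 15316, against 1 for the quasi-likelihood test. They called 48 and 39 of 100 genes changed 2-fold, against 27. The simulation drew genes independently, with 1 dispersion for both groups, whereas the real spread was larger across KO than across WT libraries. In it limma-voom called 3 of 15316 unchanged genes, but it made up to 1448 calls on other splits of the real libraries. The simulated rates therefore need not hold for these data. In 828 gene clusters (5.12%) every KO library lay below every WT library. In 572 (3.54%) every KO library lay above, where chance gives 1.43% in each direction. The chance values of 809 and 1.43% are averages. Gene clusters vary together and other splits of the libraries were not counted in this way. The excess alone therefore does not show a difference between genotypes.

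The gene clusters next in order of p separated the groups without overlap but missed the threshold, each with an adjusted p of 0.0823 in the quasi-likelihood test. Cluster uc007wgp.1 was at 25.8 CPM ± 1.75 (SD, n = 4) in WT and 60.0 CPM ± 13.5 (SD, n = 4) in KO, a log2 difference of 1.22 with a standard error of 0.17. Cluster uc009mjb.1,uc009mjc.1 was at 7.18 CPM ± 2.59 (SD, n = 4) in WT and 0.872 CPM ± 0.312 (SD, n = 4) in KO, a log2 difference of -3.03 with a standard error of 0.42. Cluster uc009rrg.1 was at 132 CPM ± 10.1 (SD, n = 4) in WT and 58.4 CPM ± 12.8 (SD, n = 4) in KO, a log2 difference of -1.18 with a standard error of 0.17. KO replicate 1 lay with the other KO libraries on all 4 of these gene clusters. They were chosen by p over all 8 libraries, KO replicate 1 included, which favours such separation. It is therefore no separate evidence on that library. All 3 that missed the threshold passed it with DESeq2, limma-voom and the edgeR exact test, and with KO replicate 1 left out.

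**Figure D1:**
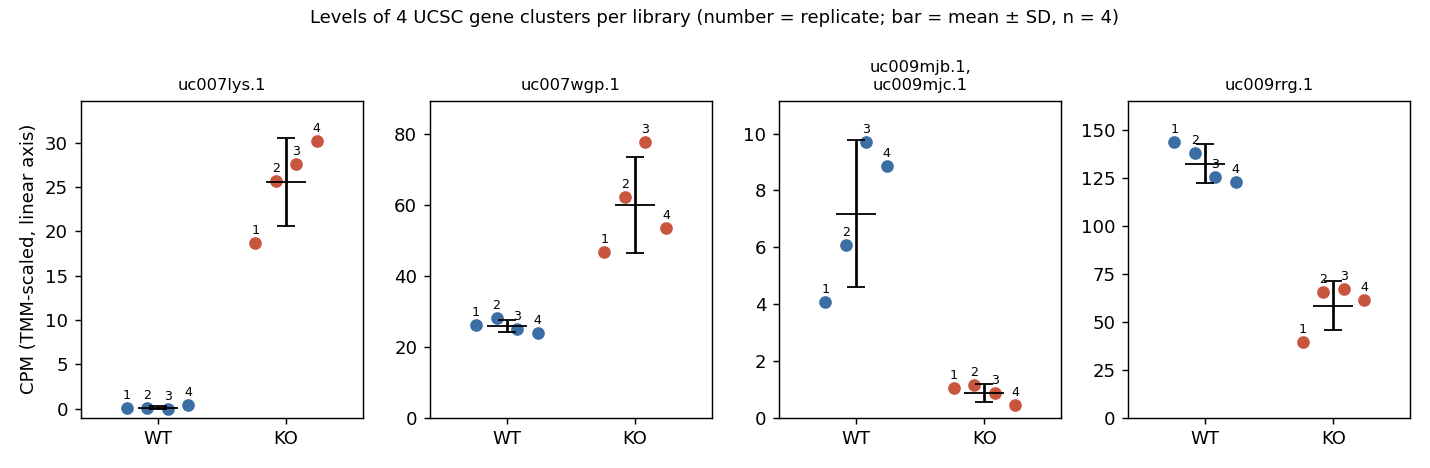
CPM (vertical axis, linear, TMM-scaled) of the 4 gene clusters in the WT and KO groups, 1 point per library with its replicate number, and bars for mean ± SD (n = 4 per group). Cluster uc007lys.1 is between 18.7 and 30.2 CPM in the KO libraries and at most 0.375 CPM in the WT libraries, and on the other 3 clusters no KO point overlaps a WT point.

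KO libraries were less alike than WT libraries, by a test that did not pass with Spearman's correlation or with KO replicate 1, 2 or 3 left out. The mean correlation of log2 CPM between libraries was 0.970 for the 6 WT pairs and 0.932 for the 6 KO pairs, and 0.936 for the 16 pairs of 1 WT and 1 KO library. The difference between the within-group means was 0.0384 (two-sided exact permutation test over the 8 libraries, p = 0.0286, the smallest the design allows). Without KO replicate 1 it was 0.0298 (exact permutation p = 0.2), without KO replicate 2 it was 0.0435 (p = 0.0857), and without KO replicate 3 it was 0.0357 (p = 0.0571). With Spearman's rho it was 0.0254 (exact permutation p = 0.0571). The biological coefficient of variation, the relative spread between libraries beyond counting noise, was 0.236 across WT libraries and 0.518 across KO libraries. It was 0.468 across KO replicates 2 to 4.

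KO replicate 1 lay with the WT libraries on the first principal component but not on the second. On the first principal component, with 48.7% of the variance, the WT libraries lay between -50.3 and -39.5 and KO replicate 1 at -45.5, while KO replicates 2, 3 and 4 lay at 17.3, 122 and 85.9. On the second, with 13.1% of the variance, the WT libraries lay between -12.2 and 2.04 and the KO libraries at 36.6, -46.2, -32.7 and 63.4. The mean correlation with the 4 WT libraries was 0.953 for KO replicate 1 and 0.950 for KO replicate 2, against 0.915 and 0.926 for KO replicates 3 and 4. By Spearman's rho, KO replicate 2 was closer than KO replicate 1 to each WT library (0.965 to 0.973 against 0.964 to 0.966). At equal depth, 20030 gene clusters had at least 1 read in KO replicate 1, against 18289, 17299 and 18173 in KO replicates 2 to 4 and between 19735 and 20064 in the WT libraries. The mean was 19918 ± 152 (SD, n = 4) in WT and 18448 ± 1144 (SD, n = 4) in KO, a difference of 1470 that did not pass the test (two-sided exact permutation p = 0.114). Without KO replicate 1 the difference was 1997 (exact permutation p = 0.0286), but this library stands out by its own detection, so that p is not an independent test.

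**Figure D2:**
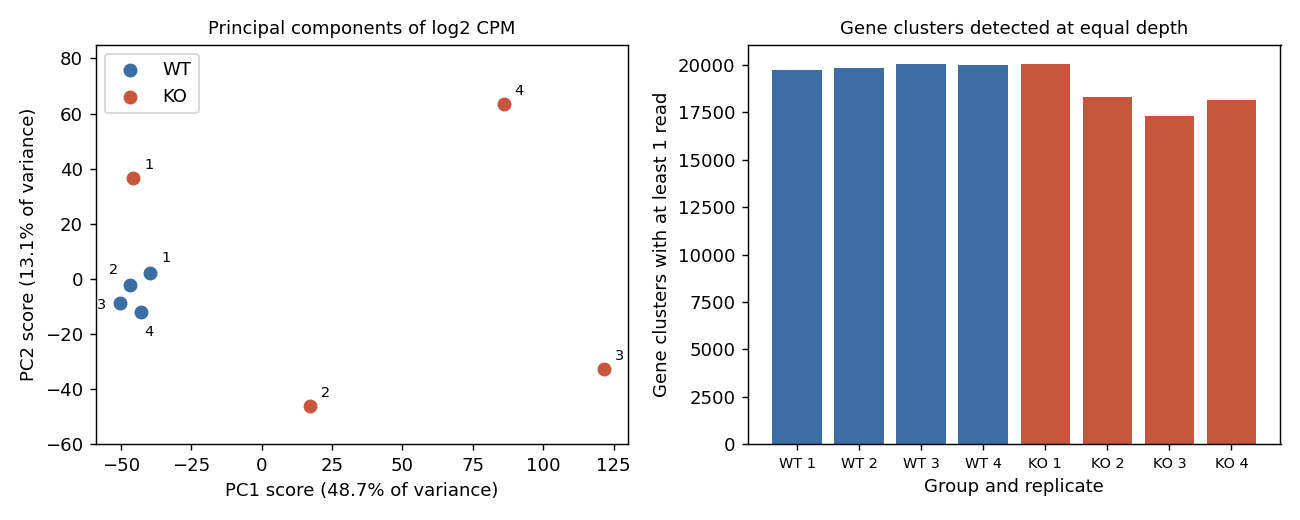
Left, scores of the 8 libraries on the first and second principal components of log2 CPM, coloured by group and numbered by replicate. Right, gene clusters with at least 1 read (bars from 0) in each library after thinning to the same depth. KO replicate 1 lies among the WT libraries on the first component and has 20030 detected gene clusters, within the WT range of 19735 to 20064.

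With KO replicate 1 left out, an alternative planned with the other leave-one-out fits, 441 gene clusters rose and 442 fell in KO replicates 2 to 4 against the 4 WT libraries (edgeR quasi-likelihood test, adjusted p under 0.05, 16496 tested). Leaving out any other library alone gave 1 higher and 0 lower. With KO replicate 1 and any 1 WT library left out, or with WT replicates 3 and 4 summed into 1 library, between 1 and 2 rose and between 1 and 8 fell. The median log2 fold changes of the 441 and 442 gene clusters in these fits of 3 against 3 were 0.60 to 0.68 and -2.26 to -2.12. The gene clusters had been chosen from the same libraries, so these medians are not a separate test of the changes. The gene clusters that rose were well expressed and moved little. Their median level was 46.1 CPM in WT and 72.7 CPM in KO replicates 2 to 4, with a median log2 fold change of 0.66 (quartiles 0.56 and 0.78), and 31 of the 441 changed at least 2-fold. Those that fell had lower levels than those that rose, and moved further. Falls were not confined to low levels: they were called in 1.81% of gene clusters at a WT mean of 50 CPM or more. Below 50 CPM they were called in 2.92%. Their median level was 6.02 CPM in WT and 1.10 CPM in KO replicates 2 to 4, with a median log2 fold change of -2.31 (quartiles -4.23 and -1.11). At least 2-fold changes were found in 354 of the 442 and at least 8-fold changes in 177. These falls came with the lower number of gene clusters detected in KO replicates 2 to 4.

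KO replicate 1 lay nearer to the WT mean than to the mean of KO replicates 2 to 4 on most of these gene clusters. It was past the midpoint toward KO in 58 of the 441 and 126 of the 442. On a scale from the WT mean at 0 to the mean of KO replicates 2 to 4 at 1, its median position was -0.022 over the gene clusters that rose and 0.196 over those that fell. Each library was also held out and placed between the means of the remaining WT and KO libraries. This used the 300 gene clusters of each direction with the smallest p without it. Over the falls, WT libraries lay at -0.016 to 0.187, KO replicate 1 at 0.214 and KO replicates 2 to 4 at 0.576 to 1. Over the rises, the same sets lay at 0.070 to 0.422, -0.0019 and 0.700 to 0.859. The 0.196 alone therefore shows no shift toward KO. KO replicate 1 was on the KO side of the WT mean in 208 of the 441 that rose and in 284 of the 442 that fell. It lay beyond every WT library on the KO side in 113 (25.6%) and 214 (48.4%) of them. A further WT library would also lie beyond the others on some gene clusters, and that share was not measured. Over the 177 gene clusters that fell at least 8-fold, its median level was 66.8% of the WT mean (quartiles 48.6% and 95.9%).

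**Figure D3:**
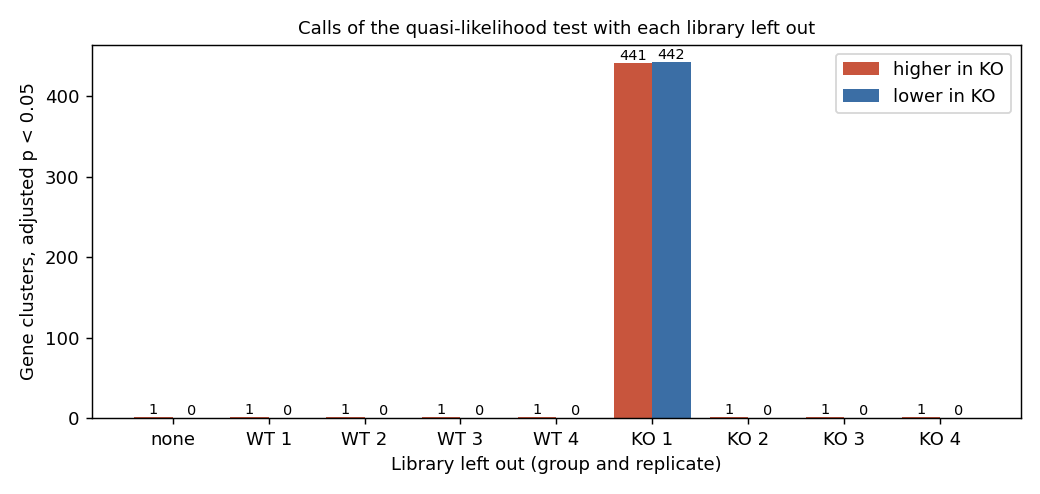
Number of gene clusters higher and lower in KO with an adjusted p under 0.05 in the edgeR quasi-likelihood test (bars from 0), for the fit of all libraries (none) and for each fit with 1 library left out. Without KO replicate 1 the counts are 441 and 442, and in every other fit shown they are 1 and 0.

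The balance of the calls made without KO replicate 1 depended on how libraries were scaled. With TMM, 49.9% of the calls were higher in KO, with RLE factors 39.7% (255 higher, 388 lower), and with library size alone 9.42% (47 higher, 452 lower). The median log2 fold change of all gene clusters was 0.0048 with TMM and -0.18 with library size alone, so the smaller rises are relative to that shift. Of the 441 that rose, 47 were also called with library size alone, 255 with RLE factors, 437 with limma-voom and 441 with DESeq2. All 441 still rose with library size alone, where their median log2 fold change was 0.47 (quartiles 0.37 and 0.58) and their median adjusted p was 0.0986. Of the 442 that fell, 379 were also called with library size alone, 386 with RLE factors, 357 with limma-voom and 442 with DESeq2.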

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

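The total count of KO replicate 1, 23912043, was far from the other KO libraries. Its gap to the nearest of them was 0.838 of the group's range, above Dixon's 95% critical value for 4 samples. It was the only one of 22 sets of 4 values tested to pass that value, and chance alone passes about 1 in 20. The deepest library held 28643310 counts. Gene detection was compared after thinning to equal depth.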

How the results depend on the processing

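The exact test, the comparisons of detection and correlation, the summing of WT replicates 3 and 4, and the other tools, scalings and libraries left out beside KO replicate 1 were chosen after seeing the data. Cluster uc007lys.1 was higher in KO in all 18 alternatives (log2 fold change 7.22 to 9.26) and passed the threshold in 17, all except the fit with a replicate block (adjusted p = 0.0672). The other 3 named clusters kept their direction in every alternative that tested them and passed the threshold in 5 of 18, 4 of 17 and 6 of 18. The quasi-likelihood counts of 1 higher and 0 lower stayed the same with RLE factors, with no low-count filter, without robust estimation and with WT replicates 3 and 4 summed into 1 library. Library size alone gave 1 and 5 and moved the median log2 fold change of all gene clusters from 0.029 to -0.11. A filter of 5 CPM in 4 libraries gave 2 and 6, with fewer gene clusters tested (10263). DESeq2 gave 114 and 260 (2554 adjusted p not available), limma-voom with quality weights 158 and 282, and the edgeR exact test 37 and 150. DESeq2 and limma-voom shared 219 calls, and 226 and 283 of their calls were among the 883 made without KO replicate 1. The cause of these differences between tools was not tested. The replicate block gave 0 and 0, but same-numbered libraries did not deviate together (-0.065 to -0.00017) and no WT library deviated most like the KO library of its own number. Leaving out 1 library gave 1 to 441 higher and 0 to 442 lower, the upper ends without KO replicate 1. With KO replicate 1 left out, RLE factors gave 255 and 388, library size alone 47 and 452, squared TMM factors, which shift fold changes upward, 1867 and 552, limma-voom 1122 and 872, and DESeq2 1124 and 1449. With KO replicate 1 and WT replicate 1, 2, 3 or 4 left out, the counts were 1 and 3, 2 and 8, 1 and 1, and 1 and 2, and with WT replicates 3 and 4 summed they were 1 and 2, in fits of fewer libraries. The WT minus KO difference in detected gene clusters was 1087 to 1997 with 1 library left out, and 1249 at 10 reads. The difference in within-group correlation was 0.0298 to 0.0444 with 1 library left out, and 0.0254 by Spearman's rho (exact permutation p = 0.0571). Results for Xbp1 and for the fixed gene lists were not run under any alternative, since the rows carry no gene names. Depth limits only the low end: 3 counts are 0.105 to 0.125 CPM.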

Other observations

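The tests of a mislabelled library, of library complexity, of fold changes under each scaling and of a repeated library, and the exchange of KO replicate 1 with each WT library, were chosen after the result was seen. The gene clusters called without KO replicate 1 split by expression level in WT. Below a WT mean of 1 CPM, 82 of 2549 fell and 1 rose. Between 1 and 5 CPM, 122 of 3699 fell and 7 rose. Between 5 and 50 CPM, 173 of 6652 fell and 221 rose, and at 50 CPM or more 65 of 3596 fell and 212 rose.

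The first pattern is that KO replicate 1 lies close to the WT libraries on most gene clusters that separate the other KO libraries from WT. Against a WT library under a KO label, KO replicate 1 stood with KO replicates 2 to 4, at least 2-fold to 1 side of the 4 WT libraries, on 56 gene clusters, against 0 to 8 when each WT library was put in its place. WT replicates 3 and 4 gave 2 and 0, and being nearly alike they could hardly stand 2-fold apart. WT replicates 1 and 2 gave 3 and 8. Further tests held out each WT library in turn. KO replicate 1 lay past the midpoint toward KO in 21.8% to 26.6% of the 500 gene clusters with the smallest p. The held-out WT library did so in 2% to 14.6%. On 16 to 27 gene clusters with a wide gap between groups, the counts were 1 to 4 and 0 to 1. A mixture of WT and KO cells in 1 fixed proportion, as the whole cause, predicts a spread like that of matched gene clusters. Over the 177 gene clusters down at least 8-fold, the spread of the log2 level of KO replicate 1 relative to WT exceeded that of matched gene clusters by 0.15 (bootstrap 95% interval over gene clusters, which are not independent, 0.046 to 0.31). Matching was by WT mean level alone, so gene clusters that vary more between libraries could also give this excess. The test therefore does not decide on a mixture. A difference between animals remains untested, since the labels describe all KO mice alike.

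The second pattern is the rise from 1 to 883 calls when KO replicate 1 is left out. Of 35 splits of the 7 libraries, 1 gave as many as 441 higher (highest other 1) and 1 as many as 442 lower (highest other 0), but whether chance can be excluded stays open, since KO replicate 1 was singled out for giving the most calls and the other splits had no such choice: with WT replicate 1, 2, 3 or 4 left out instead, the other WT libraries and KO replicate 1 against KO replicates 2 to 4 gave 0 and 2, 0 and 1, 0 and 0, and 364 and 276. Among the lower calls, the share called at a WT mean of 50 CPM or more was 0.62 of that below (bootstrap 95% interval 0.47 to 0.79, which spans the bound of 0.5), so a loss of low-level transcripts from KO replicates 2 to 4 cannot be told apart from lower expression, and the ratio of 3.32 for the higher calls (2.75 to 4.01) decides nothing, since such a loss would raise the share of abundant transcripts. The number of calls depended on scaling: 48.2% were kept with library size alone, which lowered the median log2 fold change of the 441 higher calls from 0.66 to 0.47 (quartiles 0.37 and 0.58) at a median standard error of 0.14 in both fits, so most of them missed the threshold. What share of the higher calls scaling accounts for stays open, but it is argued against as the whole cause of the lower ones, of which 91.9% were kept with squared TMM factors, which shift fold changes upward (their median log2 fold change was -2.31 with TMM and -2.17 with squared factors, quartiles -4.08 and -0.92).

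The third pattern is that WT replicates 3 and 4 were nearly alike, with a correlation of 0.991 against 0.964 to 0.968 for other WT pairs and a coefficient of variation of 0.0565 against 0.230 for WT replicates 1 and 2. A single library deposited under 2 names, differing by sampling noise alone, is argued against by a chi-square per gene of 4.66, where such noise gives about 1. Shared handling, 1 library sequenced in separate runs, or 2 preparations from 1 mouse remains possible. This was not tested, since the labels name no batch or mouse. In the fit of KO against WT, limma-voom gave these libraries quality weights of 5.89 and 3.37, against 0.313 to 0.828 for the others.

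Over all 8 libraries, chance is argued against for the call of 1 higher gene cluster (1 of 35 splits gave as many, highest other 0). That is the smallest share that 35 splits can give, and it treats all 8 libraries as independent. For 0 lower gene clusters the count says nothing, since 35 of 35 splits give as many (highest other 0). For the 440 calls of limma-voom in both directions chance cannot be excluded, since 8 of 35 splits gave as many. The highest other, 1448, set WT replicate 1 with KO replicates 2 to 4 against the rest, and 1254 calls came from the split of WT replicate 2 with KO replicates 2 to 4 against the rest. The remaining 5 with more calls than the real split, from 557 to 1033, kept WT replicates 3 and 4 together. Counts this far above the real one point to a structure of the samples. The splits with 1448 and 1254 calls are the genotype split with KO replicate 1 exchanged for 1 WT library. All 7 with more calls than the real split keep together the libraries with the highest weights in the fit of the real split. Other splits that also keep these libraries together gave fewer calls than the real one, from 0 to 266. Limma-voom estimates the weights from the grouping it is given, so those of the other splits can differ. Whether the weights give these counts was not tested.

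The row order of the deposited table largely followed fold change. After the first 1000 rows, row number and log2 fold change had a Spearman correlation across gene clusters of -0.895 with all 8 libraries and -0.803 without KO replicate 1.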
